A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

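The series holds RNA sequencing of 36 yeast cultures, 3 in each of 12 groups made by 4 strains and 3 conditions. Per the labels, cells were grown in YPD, total RNA was extracted with a RiboPure Yeast kit, and poly-A-selected TruSeq libraries were sequenced on a NovaSeq instrument. The submitters' processing notes name Trim Galore, FastQC, STAR and Salmon and the genome build R64, with no version, role or order. The deposited table gives raw counts per gene, as whole numbers with no normalization, for 7126 genes in each of the 36 libraries. The counting tool, its strand setting and the annotation are not given in the sources used here. Groups and replicate numbers came from the labels.

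Gene positions came from the R64 RefSeq annotation, in which 6048 of the gene names were found and 1078 were not. Names of the deposited table were kept, with older symbols matched through their systematic names. Total counts ran from 8159203 to 99558095 per library. With 3 libraries per group, the spread between replicates and not the counting error limits the precision. Errors beside CPM are SDs of 3 libraries, and errors beside log2 changes are standard errors of the fit. CPM (counts scaled to library size) were adjusted by TMM, with a prior count of 2 where logs were taken for principal components and correlations.

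Testing used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed by filterByExpr by group, which left 6109 genes. TMM scaling factors were computed, and 1 quasi-likelihood model of 12 group means was fitted to all 36 libraries, with no block for replicate number. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 change of at least 1 (2-fold). The 19 contrasts were each treatment against the untreated libraries of its strain, untreated strains against each other, the difference of responses between strains (interactions), and AzC against heat shock in WT. Shares of genes called in one strain that responded less in another were counted from genes chosen in libraries that the interaction does not use. The overlap of heat-shock and AzC calls in WT was set beside the product expected of independent lists.

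There were 17 gene lists: Hsf1-target chaperones, cassette chaperones, Msn2/4-target stress genes, proteasome, cytosolic ribosomal proteins, ribosome biogenesis, ER folding, Gcn4-target amino acid biosynthesis, proline metabolism, methionine and sulfur assimilation, Yap1-target oxidative stress, glycolysis, respiratory chain, G1/S, G2/M, histones and cell wall integrity. Each was tested by camera from limma with a preset correlation between genes of 0.01, adjusted over the 17 lists of a contrast, and again with a correlation estimated from the data. List members were counted as risen or fallen at an adjusted p below 0.05 with no fold minimum, over all genes tested and adjusted over the list alone. In contrasts between strains, treatments or responses, risen and fallen (or up and down) give the sign of the difference. Lists of mating-type genes served as markers of other cells. The lists, the tests, the thresholds, the rule for named genes and the alternatives were chosen before the data were examined, except 3 alternatives named with the settings and the tests named as later ones.

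The genes named in each comparison follow 1 rule. It allows a fixed set (HSF1, MSN2, MSN4, HIS3, LEU2, URA3, MET17, LYS2, HSP82, SSA1, SSA4, HSP104, HSP42, HSP26, SSA3, SIS1, BTN2, CUR1, CTT1, HSP12, TPS1, DDR2, RPN4, GCN4, YDJ1, HSC82, SSA2 and KAR2). It adds the 5 largest and 5 smallest log2 changes among called genes with a mean of at least 10 CPM whose replicates do not overlap between the groups, a condition dropped for interactions. It also adds, for each list, the 3 members with the smallest p and the member with the largest change against the list median. A selection of these genes is printed, and REE1 is named outside the rule.

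The alternatives were RLE size factors, scaling by library size alone, no low-count filter, DESeq2 1.42.0, replicate number as a block, a fit to the compared groups alone, leaving out each library in turn, WT in place of HSF1+ as the reference of the hsf1∆ interactions, no fold minimum on the shares, and the estimated correlation for lists. Added after the data were seen were thinning the 4 deep libraries (WT untreated 2 and 3, HSF1+ AzC 1 and 2) to the median total, replicates 2 and 3 alone, and protein-coding genes alone. The model was tested on simulated data with known changes. At a 2-fold change and an adjusted p alone it recovered 100% of genes in the WT heat-shock contrast, 94% in the hsf1∆ AzC contrast and 91% in the hsf1∆ interaction under AzC (61.2%, 44.8% and 46.3% with the 2-fold minimum), with a false share of 4.57%, 5.15% and 5.08%.

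Equal replicate numbers were checked for pairing through the correlation of deviations from the group means, over genes. All 3 same-numbered correlations were over 0.1 for heat shock and AzC in WT (0.117 to 0.361 and 0.163 to 0.38), for AzC against heat shock in WT (0.236 to 0.505) and for untreated hsf1∆, HSF1+ and the strain labelled msn2/4∆ against WT (0.164 to 0.265, 0.15 to 0.337 and 0.19 to 0.307). In these 6 contrasts the data pair the numbers, though the labels state no shared batch or day, and the block gave 2244, 1315, 1084, 732, 463 and 38 calls. Figures were drawn with matplotlib 3.10.9.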

Results

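RNA was sequenced from budding yeast (Saccharomyces cerevisiae, mating type a) of 4 strains under 3 conditions, with 3 libraries in each of the 12 groups and 36 libraries in all. Cells were left untreated at 25 °C, shifted to 37 °C for 15 min (heat shock), or given 10 mM azetidine-2-carboxylic acid (AzC) for 1 h at 25 °C. AzC is a proline analog that is built into new proteins in place of proline and makes them misfold. Heat shock transcription factor Hsf1 drives chaperone genes, and the paired factors Msn2 and Msn4 drive general stress genes. Besides the wild type (WT) there was a strain lacking HSF1 (hsf1∆), kept alive by a cassette that expresses the chaperone genes YDJ1, HSC82 and SSA2 constitutively, a strain with the same cassette and an intact HSF1 gene (HSF1+), and a strain labelled as lacking MSN2 and MSN4 (labelled msn2/4∆). The HSF1+ strain is the control that matches hsf1∆ for the cassette.

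Total counts ran from 8159203 to 99558095 per library, with a median of 13193875. For 32 libraries the total was at most 15448180. The other 4 held at least 42724231 each, and these were WT untreated replicates 2 and 3 and HSF1+ AzC replicates 1 and 2. After the low-count filter 6109 of 7126 genes were tested.

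The deleted genes were read at these levels in untreated cells, in counts scaled to library size (CPM, mean ± SD, n = 3). HSF1 (YGL073W, chromosome VII, 368753 to 371254, build R64) gave 98.4 ± 3.76 in WT, 55.4 ± 1.52 in HSF1+ and 14.6 ± 2.15 in hsf1∆, so reads of the deleted gene were reduced but not absent. MSN2 (YMR037C, chromosome XIII, 344403 to 346517) gave 132.4 ± 3.12 in WT and 1.41 ± 0.596 in the strain labelled msn2/4∆. MSN4 (YKL062W, chromosome XI, 323228 to 325120) gave 38.4 ± 7.53 in WT and 52.9 ± 4.82 in the strain labelled msn2/4∆, so these libraries show loss of the MSN2 transcript but not of the MSN4 transcript. Below, "labelled msn2/4∆" carries that limit. The cassette gene HSC82 (YMR186W) gave 3295 ± 468 in WT, 7464 ± 352 in HSF1+ and 3200 ± 469.8 in hsf1∆. HSC82 and SSA2 have close paralogs, HSP82 and SSA1, and how the deposited counts treat reads shared by a pair is not given in the sources used here.

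**Figure D1:**
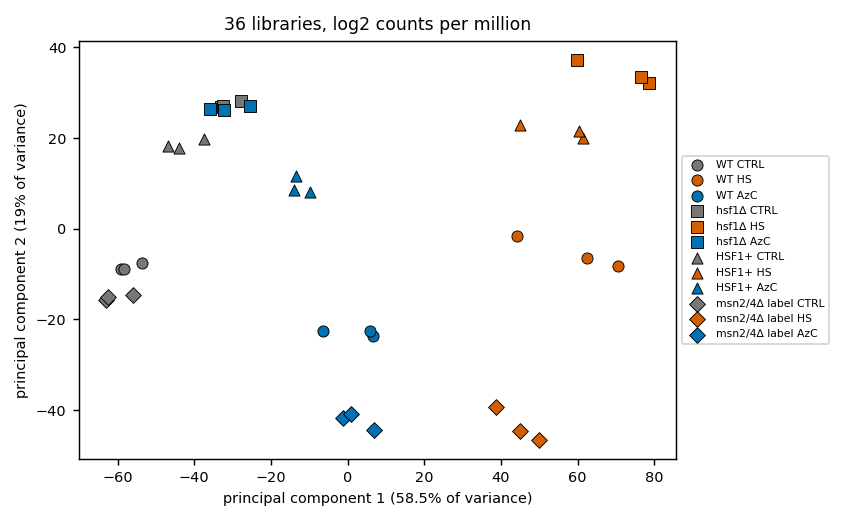
Principal components 1 (horizontal, 58.5% of the variance) and 2 (vertical, 19% of the variance) of log2 CPM, with 1 point per library, colour for the condition and shape for the strain. The hsf1∆ AzC libraries lie among the hsf1∆ untreated libraries, while the AzC libraries of the other strains lie apart from their untreated libraries.

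The first comparison asks what heat shock changed in WT. Chaperone genes were among those that rose most. SSA4, the inducible cytosolic Hsp70 (YER103W, chromosome V, 364589 to 366517), rose from 54.7 ± 9.92 to 20200 ± 3333 CPM, a log2 change of 8.52 ± 0.24 (± standard error, 3 libraries per group, edgeR quasi-likelihood adjusted p = 2.04e-21). The small heat-shock protein gene HSP26 rose by 9.66 ± 0.41, the disaggregase gene HSP104 by 5.55 ± 0.21, the inducible Hsp90 gene HSP82 by 4.65 ± 0.19 and the J-protein gene SIS1 by 2.89 ± 0.12 on the log2 scale. Genes for ribosomes fell, as RPL9A at -4.75 ± 0.37, RPS26B at -4.63 ± 0.36 and RPA190, the largest subunit of RNA polymerase I, at -4.59 ± 0.40. Other large changes were a rise of 8.44 ± 0.49 for YNL194C and falls at -4.66 ± 0.20 for the endonuclease gene HO and -4.62 ± 0.17 for the flavohemoglobin gene YHB1.

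All 21 Hsf1-target chaperone genes rose (also adjusted over the list alone). Their median was 2.89 (camera adjusted p = 6.12e-21, 0.0674 with an estimated correlation). HSP42 at 6.64 ± 0.26 and SSA1 at 3.59 ± 0.15 were among them. All 25 Msn2/4-target stress genes rose too (also adjusted over the list alone). The median was 5.15 (camera adjusted p = 8.46e-15, 0.193 with an estimated correlation). Examples were HSP12 at 9.15 ± 0.67, DDR2 at 7.11 ± 0.43, SOL4 at 7.90 ± 0.37, catalase T gene CTT1 at 5.46 ± 0.34 and trehalose-6-phosphate synthase gene TPS1 at 3.80 ± 0.19. All 33 proteasome genes rose (also adjusted over the list alone). Their median was 0.71 (camera adjusted p = 1.23e-06, 0.259 with an estimated correlation), with RPN7 at 0.97 ± 0.06. The proteasome activator gene RPN4, on that list, rose by 0.79 ± 0.15. In the list of 138 cytosolic ribosomal protein genes, 1 rose, 99.3% fell and 0 did not pass (1 up and 99.3% down adjusted over the list alone). The median was -3.47, with a camera adjusted p = 2.55e-55 (adjusted p = 0.117 with an estimated correlation), RPS11B at -3.33 ± 0.13 and RPL38 at -3.49 ± 0.14 being examples and RPL15B at 0.59 ± 0.06 the exception. All 40 ribosome biogenesis genes fell (also adjusted over the list alone). Their median was -2.91 (camera adjusted p = 6.67e-06, 0.443 with an estimated correlation). Among 12 ER folding genes, 9 rose, 0 fell and 3 did not pass (9 up and 0 down adjusted over the list alone). The median was 0.75, with a camera adjusted p = 0.0181 (adjusted p = 0.427 with an estimated correlation), including the ER Hsp70 gene KAR2 at 2.73 ± 0.14 and MPD1 at 1.76 ± 0.12. Among 30 Gcn4-target biosynthetic genes, 7 rose, 18 fell and 5 did not pass (7 up and 18 down adjusted over the list alone). Their median was -0.57, with a camera adjusted p = 0.0107 (adjusted p = 0.438 with an estimated correlation).

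Cell-cycle and histone genes fell as well. All 12 G1/S genes fell (also adjusted over the list alone). The median was -1.61, with a camera adjusted p = 3.31e-07 (adjusted p = 0.117 with an estimated correlation), with the cyclin gene CLN2 at -2.86 ± 0.13 and the DNA polymerase gene POL1 at -1.98 ± 0.09. For 11 G2/M genes, 0 rose, 9 fell and 2 did not pass (0 up and 9 down adjusted over the list alone). Their median was -0.64, with a camera adjusted p = 0.0181 (adjusted p = 0.259 with an estimated correlation). For 8 histone genes, 0 rose, 7 fell and 1 did not pass (0 up and 7 down adjusted over the list alone). The median was -1.38, with a camera adjusted p = 0.00605 (adjusted p = 0.427 with an estimated correlation). Respiratory chain genes went up by count, as 27 rose, 3 fell and 3 did not pass (27 up and 3 down adjusted over the list alone). Their median was 0.75, with a camera adjusted p = 0.0123 (adjusted p = 0.615 with an estimated correlation). For the 11 cell wall integrity genes, 10 rose, 1 fell and 0 did not pass (10 up and 1 down adjusted over the list alone). The median was 1.93, with a camera adjusted p = 0.00286 (adjusted p = 0.259 with an estimated correlation). The remaining lists passed no camera test. In the Yap1-target oxidative stress list 8 rose and 4 fell of 13 (camera adjusted p = 0.223), with the peroxiredoxin gene TSA2 at 4.19 ± 0.11 and the peroxidase gene GPX2 at -1.90 ± 0.11. The corresponding counts were 4 and 8 of 16 for glycolysis (adjusted p = 0.463), 3 and 11 of 19 for methionine and sulfur assimilation (adjusted p = 0.119), 3 and 3 of 6 for proline metabolism (adjusted p = 0.937, median 0.42 with a camera direction of down) and 3 and 0 of 3 for the cassette chaperones (adjusted p = 0.121). HSF1 itself rose by 1.02 ± 0.13 and MSN4 by 1.58 ± 0.11. In all, edgeR called 2233 genes at an adjusted p below 0.05 and at least 2-fold change, 1178 higher and 1055 lower. The heat-shocked replicate 1 libraries of all 4 strains responded less than replicates 2 and 3, with slopes on the mean response of 0.968, 1.146 and 1.221 for WT replicates 1 to 3.

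**Figure D2:**
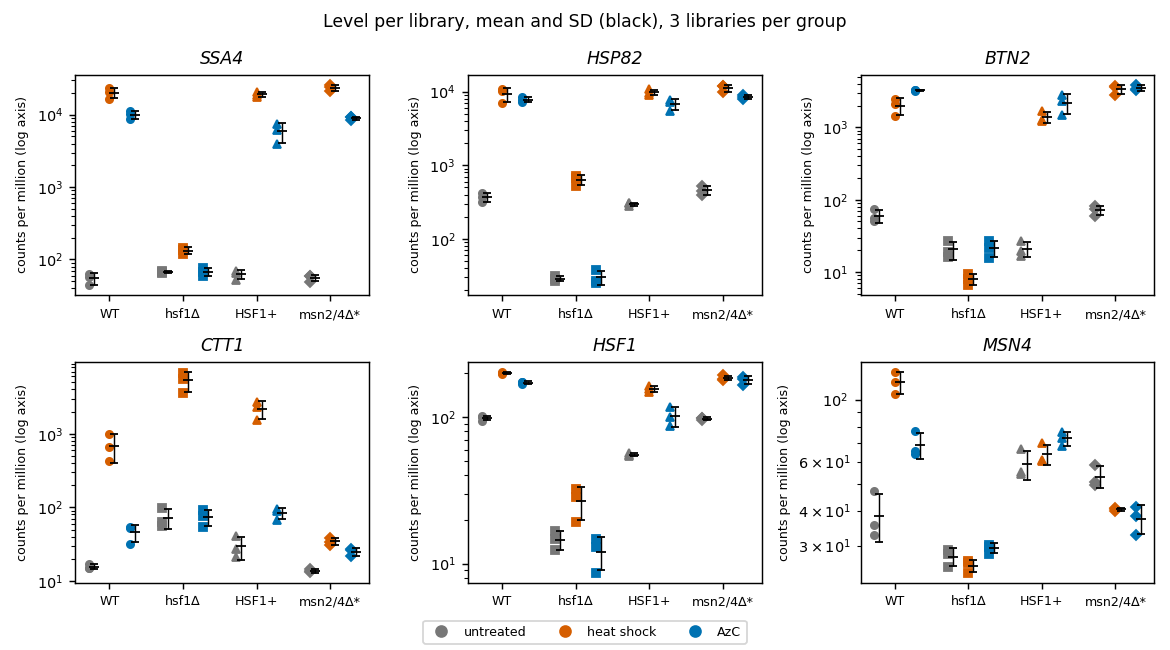
CPM (vertical, log axis) of 6 genes in each library, grouped by strain along the horizontal axis, where the asterisk marks the strain labelled msn2/4∆; coloured points are libraries and black marks the mean and SD of 3. SSA4 in hsf1∆ stays below 200 CPM in every condition, and MSN4 is present in the strain labelled msn2/4∆.

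The second comparison asks what AzC changed in WT. The largest rises were those of SSA4 at 7.51 ± 0.23 (log2 change ± standard error, 3 libraries per group), HSP42 at 6.69 ± 0.26, HSP12 at 6.31 ± 0.59, HSP26 at 5.86 ± 0.35 and RTC3 at 5.81 ± 0.26. BTN2 and CUR1, which encode sorting factors for misfolded proteins, rose by 5.76 ± 0.28 and 3.41 ± 0.20. HSP104 rose by 5.03 ± 0.20, HSP82 by 4.38 ± 0.19, SSA1 by 3.97 ± 0.16 and SIS1 by 2.63 ± 0.12. The largest falls were in the adenine deaminase gene AAH1 at -3.53 ± 0.44, GFD2 at -3.28 ± 0.35, the purine salvage gene HPT1 at -3.25 ± 0.35, the pentose phosphate gene RKI1 at -3.23 ± 0.32 and the helicase gene DBP2 at -3.19 ± 0.76.

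In the Hsf1-target list 21 rose, 0 fell and 0 did not pass (21 up and 0 down adjusted over the list alone). Their median was 2.99, with a camera adjusted p = 1.08e-44 (adjusted p = 0.00103 with an estimated correlation). Of 33 proteasome genes 33 rose, 0 fell and 0 did not pass (33 up and 0 down adjusted over the list alone). The median was 0.92, with a camera adjusted p = 1.14e-25 (adjusted p = 0.00968 with an estimated correlation), with RPN11 at 1.23 ± 0.06, RPT2 at 1.21 ± 0.07, PRE3 at 1.06 ± 0.06 and the activator RPN4 at 1.36 ± 0.15. Among the Msn2/4-target genes 24 rose, 0 fell and 1 did not pass (24 up and 0 down adjusted over the list alone). Their median was 2.69, with a camera adjusted p = 2.61e-13 (adjusted p = 0.249 with an estimated correlation), CTT1 at 1.55 ± 0.30, TPS1 at 2.29 ± 0.18 and DDR2 at 3.64 ± 0.38 included. Among the 3 cassette chaperone genes 3 rose, 0 fell and 0 did not pass (3 up and 0 down adjusted over the list alone). The median was 1.78, with a camera adjusted p = 0.00251 (adjusted p = 0.075 with an estimated correlation). Ribosomal protein genes mostly fell, as 1 rose, 98.6% fell and 1 did not pass (1 up and 98.6% down adjusted over the list alone). Their median was -1.40, with a camera adjusted p = 9.31e-28 (adjusted p = 0.301 with an estimated correlation), with RPS28B at -1.93 ± 0.14. Of the ribosome biogenesis genes 0 rose, 40 fell and 0 did not pass (0 up and 40 down adjusted over the list alone). The median was -2.23, with a camera adjusted p = 2.93e-07 (adjusted p = 0.437 with an estimated correlation). Of the ER folding genes 11 rose, 0 fell and 1 did not pass (11 up and 0 down adjusted over the list alone). Their median was 0.63, with a camera adjusted p = 0.000474 (adjusted p = 0.301 with an estimated correlation), with KAR2 at 2.34 ± 0.14 and the ER oxidase gene ERO1 at 2.87 ± 0.23. Of the Gcn4-target genes 3 rose, 19 fell and 8 did not pass (3 up and 19 down adjusted over the list alone). The median was -0.60, with a camera adjusted p = 0.00019 (adjusted p = 0.336 with an estimated correlation), with HIS4 at -1.50 ± 0.10. Of the histone genes 0 rose, 8 fell and 0 did not pass (0 up and 8 down adjusted over the list alone). Their median was -0.96, with a camera adjusted p = 0.000877 (adjusted p = 0.336 with an estimated correlation). Of the G1/S genes 0 rose, 9 fell and 3 did not pass (0 up and 9 down adjusted over the list alone). The median was -0.56, with a camera adjusted p = 0.0189 (adjusted p = 0.437 with an estimated correlation).

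In the proline metabolism list 2 rose and 3 fell of 6 (camera adjusted p = 0.698). The proline breakdown genes PUT1 and PUT2 rose by 1.97 ± 0.17 and 1.19 ± 0.08, and PRO1, which encodes the first enzyme of proline synthesis, stood at -1.18 ± 0.14. Methionine genes gave 1 up and 8 down of 19 (adjusted p = 0.0761), with methionine synthase gene MET6 at -2.30 ± 0.18 and SAM2 at -1.49 ± 0.09. The other lists passed no camera test, with 8 of 11 cell wall integrity genes up (adjusted p = 0.0696, PRM5 at 2.70 ± 0.17), 10 of 16 glycolysis genes down (adjusted p = 0.205), and for Yap1-target genes, respiratory chain and G2/M adjusted p = 0.989, 0.796 and 0.989 (G2/M median 0.04 with a camera direction of down). HSF1 rose by 0.80 ± 0.13. By edgeR 1296 genes were called, 617 higher and 679 lower, while scaling by library size alone gave 802 higher and 582 lower.

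Set directly against heat shock in WT, AzC gave lower Msn2/4-target and higher ribosomal protein genes. CTT1 was lower after AzC at -3.91 ± 0.32 (log2 AzC over heat shock ± standard error, 3 libraries per group), HSP26 at -3.80 ± 0.32, HSP12 at -2.84 ± 0.50, the hexose transporter gene HXT5 at -6.47 ± 0.30, SPG4 at -6.37 ± 0.25, FMP45 at -6.17 ± 0.32, TKL2 at -5.65 ± 0.29 and TSA2 at -3.25 ± 0.10. Higher after AzC were HO at 3.58 ± 0.20, YBR099C at 3.48 ± 0.22, HRP1 at 3.38 ± 0.13, TIR3 at 3.36 ± 0.16 and RPS26B at 2.96 ± 0.34, and among chaperone-related genes CUR1 at 1.27 ± 0.18 and BTN2 at 0.70 ± 0.23. HSP42 differed by 0.06 ± 0.20 (adjusted p = 0.824). The 21 Hsf1-target genes split, with 6 higher after AzC, 10 lower and 5 not passing (6 and 10 adjusted over the list alone). Their median was -0.26, with a camera adjusted p = 0.561. Of the Msn2/4-target genes 0 were higher, 24 lower and 1 did not pass (0 and 24 adjusted over the list alone). The median was -2.27 (camera adjusted p = 5.09e-12, 0.253 with an estimated correlation). In the ribosomal protein list 97.1% were higher, 0 lower and 4 did not pass (97.1% and 0 adjusted over the list alone). Their median was 2.05 (camera adjusted p = 6.64e-58, 0.099 with an estimated correlation). All 12 G1/S genes were higher after AzC than after heat shock (also adjusted over the list alone). The camera adjusted p was 2.23e-09 (adjusted p = 0.073 with an estimated correlation), with CLN2 at 1.93 ± 0.12 and ribonucleotide reductase gene RNR1 at 2.38 ± 0.15. In the proteasome list 24 were higher, 0 lower and 9 did not pass (25 and 0 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.00461, 0.708 with an estimated correlation), with RPN4 at 0.58 ± 0.15. The edgeR call was 1060 genes, 480 higher after AzC and 580 lower (530 and 519 scaled by library size alone, 671 and 596 without WT heat-shock replicate 1). The treatments differ in duration and temperature as well as in kind. Without WT heat-shock replicate 1 the BTN2 difference was 0.50 and no longer passed, and RPN4 did not pass with the compared groups alone (adjusted p = 0.06).

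Of the 617 genes called higher after AzC in WT, 510 (82.7%) were also called higher after heat shock, 4.29 times the number that independent lists would share. Of the 679 called lower after AzC, 631 (92.9%) were also called lower after heat shock, 5.38 times that number. Both comparisons use the same 3 untreated libraries, which can raise the overlap. In 20 simulations of unchanged genes a mean of 0 were shared, but for changed genes this was not measured.

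Heat shock was next followed in hsf1∆, which asks what remains without Hsf1. The largest rises included HXT5 at 8.28 ± 0.34 (log2 change ± standard error, 3 libraries per group), FMP45 at 6.79 ± 0.33, transketolase gene TKL2 at 6.67 ± 0.29 and HSP26 at 6.51 ± 0.37. Among Msn2/4 targets, aldehyde dehydrogenase gene ALD3 rose by 6.58 ± 0.30, CTT1 by 6.19 ± 0.35 and HSP12 by 4.56 ± 0.54. SSA4 reached 132.6 ± 14 CPM from 67.7 ± 2.57, a change of 0.97 ± 0.18, against 19030 ± 1505 in heat-shocked HSF1+ cells. BTN2 fell, at -1.36 ± 0.27, and so did the cassette gene HSC82 at -0.95 ± 0.18, while SSA2 rose by 2.04 ± 0.17. HSP82 rose by 4.45 ± 0.19 from a low start of 28.8 ± 2.33 to 632 ± 98.2 CPM.

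Of the Hsf1-target genes 12 rose, 3 fell and 6 did not pass (12 up and 3 down adjusted over the list alone). The median was 0.39, with a camera adjusted p = 0.00531 (adjusted p = 0.579 with an estimated correlation). Those that rose included HSP104 at 3.47 ± 0.19, HSP42 at 3.49 ± 0.23, SIS1 at 1.75 ± 0.12, SSA1 at 1.25 ± 0.14 and mitochondrial disaggregase gene HSP78 at 3.98 ± 0.18. All 25 Msn2/4-target genes were up by count, as 25 rose, 0 fell and 0 did not pass (25 up and 0 down adjusted over the list alone). Their median was 3.45, with a camera adjusted p = 8.34e-12 (adjusted p = 0.246 with an estimated correlation). Of proteasome genes 16 rose, 3 fell and 14 did not pass (16 up and 3 down adjusted over the list alone). The median was 0.14, with a camera adjusted p = 0.257, with RPN5 at 0.60 ± 0.07 and PUP1 at -0.30 ± 0.07. In the ER folding list 12 rose, 0 fell and 0 did not pass (12 up and 0 down adjusted over the list alone). Their median was 1.68, with a camera adjusted p = 1.01e-08 (adjusted p = 0.0829 with an estimated correlation), with MPD1 at 2.38 ± 0.12, DER1 at 1.77 ± 0.10 and KAR2 at 2.40 ± 0.14. For ribosomal protein genes 1 rose, 99.3% fell and 0 did not pass (1 up and 99.3% down adjusted over the list alone). The median was -3.83, with a camera adjusted p = 9.78e-75 (adjusted p = 0.0703 with an estimated correlation), with RPS26B at -5.71 ± 0.39. The largest other falls were INA1 at -6.04 ± 0.43 and TOS6 at -5.57 ± 0.20. By edgeR 1969 genes were called, 907 higher and 1062 lower.

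In HSF1+ cells heat shock raised HSP26 by 9.96 ± 0.42 (log2 change ± standard error, 3 libraries per group), HXT5 by 8.50 ± 0.33, SSA4 by 8.25 ± 0.24, TKL2 by 7.63 ± 0.31, SPG4 by 7.46 ± 0.23, BTN2 by 6.04 ± 0.29, CTT1 by 6.20 ± 0.35 and HSP82 by 5.05 ± 0.19. Falls were largest for TOS6 at -5.44 ± 0.20, dihydroorotate dehydrogenase gene URA1 at -4.67 ± 0.28 and INA1 at -4.65 ± 0.40. In the Hsf1-target list 21 rose, 0 fell and 0 did not pass (21 up and 0 down adjusted over the list alone). Their median was 3.09, with a camera adjusted p = 6.12e-29 (adjusted p = 0.0124 with an estimated correlation). In the Msn2/4-target list 25 rose, 0 fell and 0 did not pass (25 up and 0 down adjusted over the list alone). The median was 3.75, with a camera adjusted p = 1.07e-12 (adjusted p = 0.192 with an estimated correlation). Of the proteasome genes 33 rose, 0 fell and 0 did not pass (33 up and 0 down adjusted over the list alone). Their median was 0.51, with a camera adjusted p = 5.33e-05 (adjusted p = 0.319 with an estimated correlation). In the ribosomal protein list 1 rose, 98.6% fell and 1 did not pass (1 up and 99.3% down adjusted over the list alone). The median was -2.78, with a camera adjusted p = 1.31e-51 (adjusted p = 0.0994 with an estimated correlation). For the G1/S genes 0 rose, 12 fell and 0 did not pass (0 up and 12 down adjusted over the list alone). Their median was -2.20, with a camera adjusted p = 7.95e-14 (adjusted p = 0.0124 with an estimated correlation). For the G2/M genes 0 rose, 11 fell and 0 did not pass (0 up and 11 down adjusted over the list alone). The median was -0.85, with a camera adjusted p = 0.000109 (adjusted p = 0.0442 with an estimated correlation). The total by edgeR was 1862 genes, 916 higher and 946 lower.

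In the strain labelled msn2/4∆ the chaperone response to heat shock was present. SSA4 rose by 8.72 ± 0.24 (log2 change ± standard error, 3 libraries per group), HSP42 by 7.53 ± 0.27, HSP26 by 7.69 ± 0.39, HSP104 by 5.93 ± 0.21 and HSP82 by 4.62 ± 0.19. ARO10, a decarboxylase gene, rose by 7.52 ± 0.42. The Msn2/4 target HSP12 rose by 8.10 ± 0.71, CTT1 by 1.33 ± 0.31, TPS1 by 1.22 ± 0.18 and DDR2 by 3.32 ± 0.55. The ribosome assembly genes NOP7 and KRE33 stood at -5.79 ± 0.55 and -5.63 ± 0.49, and RKI1 at -5.72 ± 0.39. Among Hsf1-target genes 21 rose, 0 fell and 0 did not pass (21 up and 0 down adjusted over the list alone). Their median was 3.27, with a camera adjusted p = 2.03e-28 (adjusted p = 0.0136 with an estimated correlation). Among Msn2/4-target genes 22 rose, 0 fell and 3 did not pass (22 up and 0 down adjusted over the list alone). The median was 1.88, with a camera adjusted p = 0.00016 (adjusted p = 0.514 with an estimated correlation). Among ribosome biogenesis genes 0 rose, 40 fell and 0 did not pass (0 up and 40 down adjusted over the list alone). Their median was -4.21, with a camera adjusted p = 1.17e-09 (adjusted p = 0.457 with an estimated correlation). MSN4 itself fell by 0.39, a call lost with scaling by library size alone. EdgeR called 1990 genes, 1031 higher and 959 lower, and with that scaling the median gene moved by 0.27 in log2, against 0.11 with the scaling used here.

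After AzC, hsf1∆ cells showed almost no measured change. SSA4 stood at 67.4 ± 7.74 CPM against 67.7 ± 2.57 untreated, a log2 difference of -0.01 ± 0.18 (± standard error, 3 libraries per group). The differences for HSP82, HSP104 and HSP42 were 0.07 ± 0.17, 0.12 ± 0.17 and 0.08 ± 0.21, each with an adjusted p of 1. The proline oxidase gene PUT1 differed by 0.66 ± 0.17 and HSP12 by -1.39 ± 0.48 (-0.43 without untreated replicate 3), also with an adjusted p of 1. None of the 21 Hsf1-target, 25 Msn2/4-target, 33 proteasome or 138 ribosomal protein genes passed, with list medians of 0.02, 0.05, 0.00 and -0.04 (camera direction down for the Msn2/4-target list, adjusted p = 0.936). In the ER folding list no member passed, over all genes or adjusted over the list alone, while camera gave an adjusted p of 0.00442 upward (median 0.11, adjusted p = 0.592 with an estimated correlation). In the proline list 1 gene was up adjusted over the list alone. EdgeR called 0 genes, where 174 had an unadjusted p below 0.05, and DESeq2 also called 0. At an adjusted p alone 1 gene passed, REE1 at -0.60 ± 0.09, named here after its value was seen and not passing with the compared groups alone (adjusted p = 0.11) or replicates 2 and 3 alone (0.328). In simulated data of this comparison 94% of genes changed 2-fold passed the adjusted p alone and 44.8% passed with the fold minimum, which equals their change (98.5% at 4-fold). The hsf1∆ AzC and untreated libraries were as near to each other as replicates, with a median chi-square per degree of freedom of 11.9 over 9 pairs across the groups and 14.7 over 6 pairs within them, against 440 and 32.6 in HSF1+. These libraries do not show whether AzC acted on the cells or whether their AzC labels are right, a limit on each hsf1∆ AzC value.

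In HSF1+ cells AzC raised BTN2 by 6.71 ± 0.29 (log2 change ± standard error, 3 libraries per group), SSA4 by 6.55 ± 0.22, HSP26 by 5.78 ± 0.36, HSP42 by 4.88 ± 0.24 and HSP82 by 4.53 ± 0.19. The proteasome activator gene RPN4 rose by 1.43 ± 0.16 and PUT1 by 1.93 ± 0.17. The largest falls were in the purine synthesis gene ADE17 at -2.22 ± 0.15, CIN2 at -2.08 ± 0.14, HPT1 at -1.59 ± 0.32, AAH1 at -1.53 ± 0.40 and the fatty acid desaturase gene OLE1 at -1.46 ± 0.17. Of the Hsf1-target genes 21 rose, 0 fell and 0 did not pass (21 up and 0 down adjusted over the list alone). The median was 2.83, with a camera adjusted p = 1.81e-118 (adjusted p = 7.61e-07 with an estimated correlation). Of the proteasome genes 33 rose, 0 fell and 0 did not pass (33 up and 0 down adjusted over the list alone). Their median was 0.58, with a camera adjusted p = 1.37e-30 (adjusted p = 0.0035 with an estimated correlation). In the Msn2/4-target list 23 rose, 0 fell and 2 did not pass (24 up and 0 down adjusted over the list alone). The median was 1.60, with a camera adjusted p = 2.61e-13 (adjusted p = 0.19 with an estimated correlation). For ribosomal protein genes 0 rose, 92.8% fell and 10 did not pass (0 up and 95.7% down adjusted over the list alone). Their median was -0.56, with a camera adjusted p = 2.84e-15 (adjusted p = 0.369 with an estimated correlation). In all edgeR called 292 genes, 220 higher and 72 lower. Without HSF1+ AzC replicate 2 the lower genes were 39. 

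In the strain labelled msn2/4∆ AzC raised HSP42 by 7.39 ± 0.27 (log2 change ± standard error, 3 libraries per group), SSA4 by 7.33 ± 0.23, BTN2 by 5.61 ± 0.28, YJL144W by 5.53 ± 0.22, HSP104 by 5.21 ± 0.20 and HSP82 by 4.22 ± 0.18. RPN4 rose by 1.54 ± 0.16, PUT1 by 2.27 ± 0.19, TPS1 by 1.36 ± 0.18 and CTT1 by 0.86 ± 0.31, the last no longer passing without AzC replicate 1 (0.79) or replicate 2 (0.80). DBP2 stood at -4.43 ± 0.82, AAH1 at -4.18 ± 0.46, RKI1 at -4.15 ± 0.34 and MSN4 at -0.50 ± 0.11. Among Hsf1-target genes 21 rose, 0 fell and 0 did not pass (21 up and 0 down adjusted over the list alone). The median was 3.16, with a camera adjusted p = 3.59e-41 (adjusted p = 0.0016 with an estimated correlation). Of the proteasome genes 33 rose, 0 fell and 0 did not pass (33 up and 0 down adjusted over the list alone). Their median was 1.08, with a camera adjusted p = 1.34e-29 (adjusted p = 0.00464 with an estimated correlation). Of the Msn2/4-target genes 21 rose, 0 fell and 4 did not pass (21 up and 0 down adjusted over the list alone). The median was 1.19, with a camera adjusted p = 0.000755 (adjusted p = 0.461 with an estimated correlation). In the ribosomal protein list 1 rose, 98.6% fell and 1 did not pass (1 up and 99.3% down adjusted over the list alone). Their median was -1.81, with a camera adjusted p = 2.31e-39 (adjusted p = 0.203 with an estimated correlation). EdgeR called 1404 genes, 655 higher and 749 lower, with 945 and 646, and the median gene shifted by 0.25 in log2, when scaled by library size alone.

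**Figure D3:**
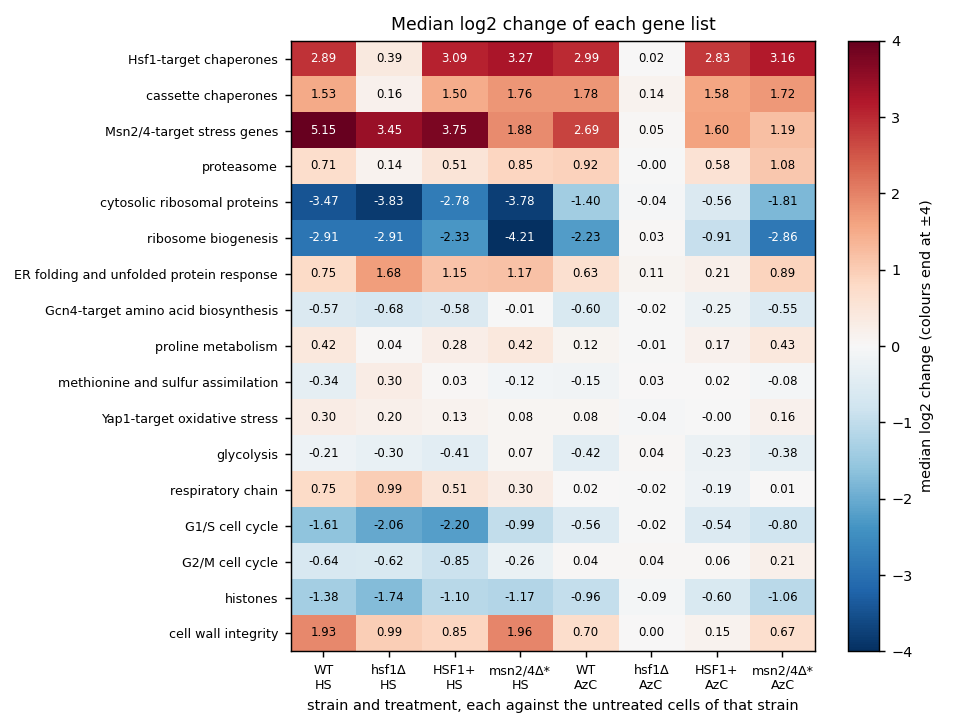
Median log2 change of each of the 17 gene lists (down the side) in each strain after heat shock (left columns) and AzC (right columns), each against the untreated libraries of the strain; red is higher and blue lower, and the asterisk marks the strain labelled msn2/4∆. The Hsf1-target chaperones have a median of 0.39 in heat-shocked hsf1∆ and 0.02 in AzC-treated hsf1∆.

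Untreated hsf1∆ and WT cells differed at many genes. Chaperone genes were lower in hsf1∆, with HSP82 at -3.68 ± 0.18 (log2 hsf1∆ over WT ± standard error, 3 libraries per group), SSA1 at -3.21 ± 0.15, SIS1 at -2.66 ± 0.12 and the Hsp90 co-chaperone gene STI1 at -2.40 ± 0.12. HSF1 reads stood at -2.75 ± 0.15. Msn2/4-target genes were higher, HSP12 at 4.70 ± 0.55, SOL4 at 4.28 ± 0.33, TSL1 at 4.20 ± 0.28, DDR2 at 3.96 ± 0.38 and CTT1 at 2.21 ± 0.30, as were the lactate dehydrogenase gene CYB2 at 4.30 ± 0.20 and PUT1 at 2.06 ± 0.18. Acid phosphatase genes PHO12 and PHO11 were at -4.98 ± 0.23 and -4.39 ± 0.22, the phosphate transporter gene PHO89 at -4.54 ± 0.47, SPL2 at -4.47 ± 0.17 and PHM6 at -4.01 ± 0.27. Of the cassette genes YDJ1 and SSA2 were higher at 0.43 ± 0.13 and 0.39 ± 0.16, 2 calls that ended without hsf1∆ replicate 2 (0.32 and 0.26) or 3 (0.26 and 0.16), the SSA2 call also without WT replicate 1 (0.31) or 3 (0.41), and HSC82 differed by -0.04 ± 0.18 (adjusted p = 0.848).

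In counts between untreated strains, rose means higher in the strain named first and fell means lower. Of the Hsf1-target genes 1 was higher in hsf1∆, 19 were lower and 1 did not pass (1 and 19 adjusted over the list alone). The median was -1.15, with a camera adjusted p = 5.23e-14 (adjusted p = 0.218 with an estimated correlation). Among Msn2/4-target genes 25 rose, 0 fell and 0 did not pass (25 up and 0 down adjusted over the list alone). Their median was 2.21, with a camera adjusted p = 7.81e-13 (adjusted p = 0.431 with an estimated correlation). Of the ribosomal protein genes 1 rose, 85.5% fell and 19 did not pass (1 up and 86.2% down adjusted over the list alone). The median was -0.95, with a camera adjusted p = 5.54e-16 (adjusted p = 0.485 with an estimated correlation). Of the Gcn4-target genes 5 rose, 16 fell and 9 did not pass (5 up and 16 down adjusted over the list alone). Their median was -0.39, with a camera adjusted p = 0.000393 (adjusted p = 0.469 with an estimated correlation). Among respiratory chain genes 19 rose, 0 fell and 14 did not pass (19 up and 0 down adjusted over the list alone). The median was 0.44, with a camera adjusted p = 0.0139 (adjusted p = 0.821 with an estimated correlation). EdgeR called 716 genes, 467 higher and 249 lower, and scaling by library size alone moved the median gene by 0.16 in log2 and left 162 lower.

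HSF1+ cells carry the cassette without the deletion, and untreated they shared part of this difference from WT. HSP12 was higher at 4.35 ± 0.54 (log2 HSF1+ over WT ± standard error, 3 libraries per group), DDR2 at 3.88 ± 0.38, TSL1 at 3.78 ± 0.27, CYB2 at 3.52 ± 0.20 and HOR7 at 3.42 ± 0.21. SPL2 was at -5.27 ± 0.18, PHO12 at -5.21 ± 0.23, PHO89 at -4.69 ± 0.47, PHO5 at -4.42 ± 0.15 and PHO11 at -4.35 ± 0.22. The cassette genes HSC82, YDJ1 and SSA2 were higher at 1.18 ± 0.18, 0.68 ± 0.13 and 0.57 ± 0.16. HSF1 itself was lower at -0.83 ± 0.14, MSN2 higher at 1.01 ± 0.12 and HSP42 higher at 1.09 ± 0.21. Among Hsf1-target genes 1 rose, 6 fell and 14 did not pass (1 up and 6 down adjusted over the list alone). Their median was -0.28, with a camera adjusted p = 0.0289 (adjusted p = 0.776 with an estimated correlation). In the Msn2/4-target list 23 rose, 0 fell and 2 did not pass (23 up and 0 down adjusted over the list alone). The median was 1.56, with a camera adjusted p = 4.55e-13 (adjusted p = 0.556 with an estimated correlation). For the respiratory chain 26 rose, 0 fell and 7 did not pass (31 up and 0 down adjusted over the list alone). Their median was 0.45, with a camera adjusted p = 7.79e-05 (adjusted p = 0.776 with an estimated correlation). By edgeR 455 genes were called, 320 of them higher.

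Between the 2 cassette strains untreated, loss of HSF1 went with lower HSP82 at -3.36 ± 0.18 (log2 hsf1∆ over HSF1+ ± standard error, 3 libraries per group), SSA1 at -3.29 ± 0.15, SIS1 at -2.29 ± 0.12, HSC82 at -1.22 ± 0.18 and HSF1 at -1.93 ± 0.15. RPL7B was at -2.49 ± 0.23, serine deaminase gene CHA1 at -2.46 ± 0.09 and ADE17 at -2.45 ± 0.15. Higher in hsf1∆ were RGI1 at 2.21 ± 0.42, the cell wall gene PIR3 at 2.05 ± 0.20, YNR034W-A at 2.05 ± 0.26, CTT1 at 1.29 ± 0.29 and PUT1 at 1.31 ± 0.18. Of the Hsf1-target genes 0 rose, 15 fell and 6 did not pass (0 up and 15 down adjusted over the list alone). The median was -0.79, with a camera adjusted p = 2.95e-19 (adjusted p = 0.0642 with an estimated correlation). Of the ribosomal protein genes 0 rose, 73.9% fell and 36 did not pass (0 up and 77.5% down adjusted over the list alone). Their median was -0.60, with a camera adjusted p = 2.25e-14 (adjusted p = 0.555 with an estimated correlation). Of the Msn2/4-target genes 10 rose, 0 fell and 15 did not pass (11 up and 0 down adjusted over the list alone). The median was 0.56, with a camera adjusted p = 0.0125 (adjusted p = 0.798 with an estimated correlation). The edgeR calls were 189 genes, 72 of them lower, and 45 lower when scaled by library size alone, where the Msn2/4-target list did not pass (adjusted p = 0.0552).

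The strain labelled msn2/4∆ was close to WT when untreated. MSN2 was at -6.58 ± 0.18 (log2 over WT ± standard error, 3 libraries per group) and MSN4 at 0.46 ± 0.11 (edgeR adjusted p = 0.0343, under 2-fold). MSN4 did not pass without WT replicate 1 (0.36) or 2 (0.40), or without replicate 1, 2 or 3 of the labelled strain (0.49, 0.50 and 0.38). Lower were YFR052C-A at -4.91 ± 0.90, hexokinase gene HXK1 at -4.18 ± 0.38, HSP12 at -3.62 ± 0.69, LSO1 at -3.08 ± 0.36, YGP1 at -1.77 ± 0.17, the nicotinamidase gene PNC1 at -1.54 ± 0.17 and DDR2 at -2.46 ± 0.56. The DDR2 call ended without WT replicate 3 (-2.29) and without replicate 1 (-2.27), 2 (-2.60) or 3 (-2.49) of the labelled strain. Higher were PHO5 at 1.05 ± 0.13, sulfate permease gene SUL1 at 2.22 ± 0.40 (adjusted p = 0.0726 with the compared groups alone) and the sulfite reductase gene MET5 at 0.39 ± 0.09, the last not passing without WT replicate 1 (0.39) or 3 (0.37) or without replicate 1 of the labelled strain (0.37). Among Msn2/4-target genes 0 rose, 9 fell and 16 did not pass (0 up and 14 down adjusted over the list alone). Their median was -0.60, with a camera adjusted p = 5.58e-37 (adjusted p = 0.0181 with an estimated correlation). Of the methionine and sulfur genes 2 rose, 0 fell and 17 did not pass (8 up and 0 down adjusted over the list alone). The median was 0.23, with a camera adjusted p = 2.78e-08 (adjusted p = 0.0181 with an estimated correlation). No Hsf1-target gene passed over all genes tested (2 up and 1 down adjusted over the list alone). EdgeR called 33 genes, 7 higher and 26 lower.

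The difference between the heat-shock responses of hsf1∆ and HSF1+ was tested as an interaction. Chaperone genes responded less in hsf1∆, with BTN2 at -7.40 ± 0.38 (log2 difference of responses ± standard error, 3 libraries in each of 4 groups), SSA4 at -7.28 ± 0.28, the cyclophilin gene CPR6 at -3.79 ± 0.13, SSA3 at -3.48 ± 0.22 and HSP26 at -3.45 ± 0.44, as did LSO1 at -4.29 ± 0.80 (-1.03 and not called with WT as the reference). SSA1 stood at -2.33 ± 0.20, HSP104 at -1.60 ± 0.24 and the Hsp90 co-chaperone gene HCH1 at -2.62 ± 0.10. HSP82 differed by -0.59 ± 0.23 (adjusted p = 0.0694) and CTT1 by -0.01 ± 0.39 (adjusted p = 0.992). More positive in hsf1∆ were CIN2 at 3.17 ± 0.24, ADE17 at 2.70 ± 0.21 and the polyamine transporter gene TPO2 at 2.74 ± 0.59. Counts of genes that rose or fell in interactions give the sign of the difference of responses, not a change within a strain. Among Hsf1-target genes 0 responded more in hsf1∆, 18 responded less and 3 did not pass (0 and 20 adjusted over the list alone). Their median was -2.33, with a camera adjusted p = 6.01e-95 (adjusted p = 3.36e-06 with an estimated correlation). Of the Msn2/4-target genes 0 rose, 1 fell and 24 did not pass (0 up and 0 down adjusted over the list alone). The median was -0.21, with a camera adjusted p = 0.901. Among ribosomal protein genes 0 rose, 78.3% fell and 30 did not pass (0 up and 84.1% down adjusted over the list alone). Their median was -1.06, with a camera adjusted p = 1.72e-30 (adjusted p = 0.23 with an estimated correlation), with RPL8A at -2.15 ± 0.27 and RPS14B at -1.72 ± 0.17. Of the proteasome genes 0 rose, 23 fell and 10 did not pass (0 up and 29 down adjusted over the list alone). The median was -0.36, with a camera adjusted p = 1.48e-09 (adjusted p = 0.198 with an estimated correlation). ER folding genes went the other way, as 9 rose, 1 fell and 2 did not pass (9 up and 1 down adjusted over the list alone). Their median was 0.51, with a camera adjusted p = 3.56e-05 (adjusted p = 0.198 with an estimated correlation), with LHS1 at 0.80 ± 0.12 and EUG1 at 0.71 ± 0.13. The edgeR count was 282 genes, 63 higher and 219 lower. With WT in place of HSF1+ as the reference 448 genes were called.

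Of the 1178 genes called higher in heat-shocked WT, chosen without this interaction's libraries, 92 (7.81%) had a smaller response in hsf1∆ than in HSF1+ and 21 a larger one, compared with a negative interaction, which includes deeper falls, in 2.58% of the 4931 other genes. With no fold minimum on the interaction the share was 18.0% (212 genes).

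The same interaction for AzC was led by BTN2 at -6.67 ± 0.37 (log2 difference of responses ± standard error, 3 libraries in each of 4 groups), SSA4 at -6.56 ± 0.27, HSP26 at -5.59 ± 0.46, HSP42 at -4.80 ± 0.31 and HSP82 at -4.46 ± 0.25. SSA1 stood at -3.63 ± 0.21, HSP104 at -4.01 ± 0.25, CPR6 at -3.01 ± 0.12, STI1 at -3.26 ± 0.16, HSP12 at -4.34 ± 0.69, RPN4 at -1.43 ± 0.22, RPT2 at -0.75 ± 0.09 and PUT1 at -1.27 ± 0.24. More positive in hsf1∆ were ADE17 at 2.20 ± 0.21, CIN2 at 2.01 ± 0.19, malic enzyme gene MAE1 at 1.63 ± 0.33, HPT1 at 1.54 ± 0.45 and HIS4 at 1.13 ± 0.13. All 21 Hsf1-target genes fell (also adjusted over the list alone). The median was -2.88 (camera adjusted p = 1.77e-143, 9.47e-08 with an estimated correlation). All 33 proteasome genes fell (also adjusted over the list alone). Their median was -0.60 (camera adjusted p = 4.89e-31, 0.00353 with an estimated correlation). The same held for all 3 cassette genes (also adjusted over the list alone). The median was -1.45 (camera adjusted p = 1.92e-05, 0.00679 with an estimated correlation). Among Msn2/4-target genes 0 rose, 22 fell and 3 did not pass (0 up and 23 down adjusted over the list alone). Their median was -1.64 (camera adjusted p = 4.66e-14, 0.163 with an estimated correlation). In the ribosomal protein list 19 rose, 0 fell and 86.2% did not pass (10 up and 0 down adjusted over the list alone). The median was 0.51 (camera adjusted p = 2.77e-13, 0.478 with an estimated correlation). EdgeR called 221 genes, 34 higher and 187 lower. The higher ones were 76 with the compared groups alone, 64 with replicates 2 and 3 alone, and 59 and 21 without hsf1∆ AzC replicate 2 and 1. With WT as the reference 1238 genes were called. The limit on the hsf1∆ AzC libraries holds here too.

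Of the 617 genes called higher after AzC in WT, 177 (28.7%) had a smaller response in hsf1∆ than in HSF1+ and 0 a larger one, compared with a negative interaction in 10 of the 5492 other genes (0.182%). As hsf1∆ changed little, this interaction is nearly the HSF1+ response with its sign reversed. HSF1+ had 220 genes called higher (slope 0.528 on the WT change), which limits the share. With no fold minimum the share was 66.5% (410 genes).

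**Figure D4:**
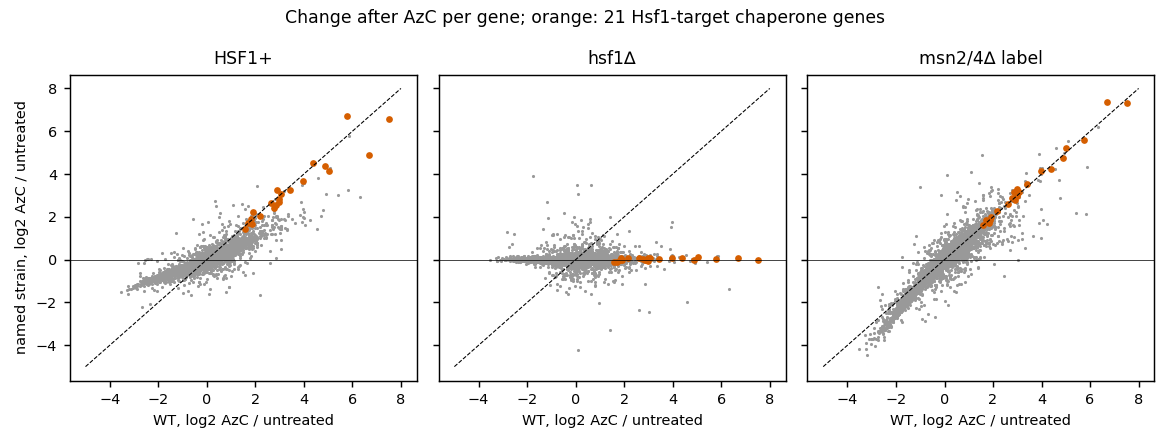
Log2 change after AzC of each tested gene in WT (horizontal) against the change in HSF1+, hsf1∆ and the strain labelled msn2/4∆ (vertical); the dashed line marks equal change and orange points are the 21 Hsf1-target chaperone genes. In hsf1∆ the chaperone points lie near the zero line, with a median of 0.02.

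The strain labelled msn2/4∆ raised Msn2/4-target genes less than WT under heat shock. CTT1 stood at -4.13 ± 0.43 (log2 difference of responses ± standard error, 3 libraries in each of 4 groups), TPS1 at -2.58 ± 0.25, SOL4 at -6.01 ± 0.65, RTN2 at -5.17 ± 0.40, phosphoglucomutase gene PGM2 at -4.99 ± 0.35, ALD3 at -4.83 ± 0.38 and DDR2 at -3.79 ± 0.84, and outside that list YNR034W-A at -7.35 ± 0.45, HSP26 at -1.97 ± 0.44 and TSA2 at -3.81 ± 0.15. MSN4 stood at -1.97 ± 0.16. SSA4 and HSP82 differed by 0.20 ± 0.25 and -0.02 ± 0.23 (adjusted p = 0.578 and 0.954), and HSP42 was at 0.89 ± 0.30. Higher were LSO1 at 3.21 ± 0.43, YDR222W at 3.15 ± 0.21 and the nucleotide synthesis gene IMD2 at 2.33 ± 0.18. Of the Msn2/4-target genes 0 rose, 21 fell and 4 did not pass (0 up and 22 down adjusted over the list alone). Their median was -3.25, with a camera adjusted p = 6.15e-38 (adjusted p = 0.0296 with an estimated correlation). Among Hsf1-target genes 4 rose, 0 fell and 17 did not pass (4 up and 0 down adjusted over the list alone). The median was 0.20, with a camera adjusted p = 0.145. Among Yap1-target genes 2 rose, 7 fell and 4 did not pass (2 up and 7 down adjusted over the list alone). Their median was -0.32, with a camera adjusted p = 0.000953 (adjusted p = 0.0445 with an estimated correlation). In the respiratory chain 0 rose, 20 fell and 13 did not pass (0 up and 23 down adjusted over the list alone). The median was -0.66, with a camera adjusted p = 5.75e-06 (adjusted p = 0.591 with an estimated correlation). EdgeR called 351 genes, 89 higher and 262 lower. HSP42, under 2-fold, did not pass the adjusted p without WT untreated replicate 3 (0.70), WT heat-shock replicate 1 (0.75), untreated replicate 1 (0.84) or 2 (0.85) of the labelled strain, or its heat-shock replicate 2 (0.81).

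Of the 916 genes called higher in heat-shocked HSF1+ cells, chosen without this interaction's libraries, 194 (21.2%) had a smaller response in the strain labelled msn2/4∆ than in WT and 14 a larger one, compared with a negative interaction, deeper falls included, in 68 of the 5193 other genes (1.31%). With no fold minimum the share was 38.8% (355 genes).

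Under AzC fewer genes differed between these strains. Smaller responses in the labelled strain were those of RTC3 at -3.66 ± 0.40 (log2 difference of responses ± standard error, 3 libraries in each of 4 groups), the glycogen phosphorylase gene GPH1 at -2.97 ± 0.50, PGM2 at -2.77 ± 0.34, TSL1 at -2.58 ± 0.36, the glycogen synthase gene GSY2 at -2.26 ± 0.35 and MSN4 at -1.33 ± 0.16. LSO1 and BOP2 were higher at 2.99 ± 0.45 and 1.10 ± 0.25. SSA4, HSP82 and HSP104 differed by -0.18 ± 0.25, -0.17 ± 0.23 and 0.18 ± 0.24 (adjusted p = 0.833, 0.822 and 0.815). Among Msn2/4-target genes 0 rose, 11 fell and 14 did not pass (0 up and 19 down adjusted over the list alone). Their median was -1.18, with a camera adjusted p = 1.28e-37 (adjusted p = 0.0319 with an estimated correlation), TPS1 at -0.93 ± 0.25 among them (adjusted p = 0.0486). No Hsf1-target gene passed, over all genes or adjusted over the list alone (median 0.07). EdgeR called 32 genes, 2 higher and 30 lower (45, 4 of them higher, without WT AzC replicate 1, and from 1 to 4 higher with a library left out). The TPS1 call ended under several settings and left-out libraries, over which it ran from -0.98 to -0.81, and BOP2 ended without untreated replicate 3 of the labelled strain (0.99), WT AzC replicate 3 (1.07) or AzC replicate 2 of the labelled strain (0.86).

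Of the 220 genes called higher after AzC in HSF1+, 22 (10.0%) had a smaller response in the strain labelled msn2/4∆ than in WT and 2 a larger one, compared with a negative interaction in 8 of the 5889 other genes (0.136%). With no fold minimum the share was 10.5% (23 genes).

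The last pair of interactions compares HSF1+ with WT, which both keep HSF1. Under heat shock HSF1+ cells had smaller responses than WT at HSP12 with -3.88 ± 0.69 (log2 difference of responses ± standard error, 3 libraries in each of 4 groups), YRO2 with -3.74 ± 0.24, DDR2 with -3.20 ± 0.48, SOL4 with -2.80 ± 0.41, GPH1 with -2.79 ± 0.40 and SSA3 with -1.05 ± 0.21. PHO11, PHO12 and PHO5 were more positive at 4.16 ± 0.34, 3.93 ± 0.32 and 2.68 ± 0.20, and LSO1 at 3.27 ± 0.48. Of the Msn2/4-target genes 0 rose, 15 fell and 10 did not pass (1 up and 19 down adjusted over the list alone). The median was -1.26 (camera adjusted p = 6.65e-17, 0.106 with an estimated correlation). Of the ribosomal protein genes 44 rose, 1 fell and 93 did not pass (74.6% up and 1 down adjusted over the list alone). Their median was 0.68 (camera adjusted p = 4.41e-25, 0.266 with an estimated correlation). For Hsf1-target genes 1 rose, 1 fell and 19 did not pass (3 up and 1 down adjusted over the list alone). The median was 0.04, with a camera adjusted p = 0.665. EdgeR called 166 genes, 40 of them higher (23 with the compared groups alone), and 341 (191 higher) without WT heat-shock replicate 1.

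Under AzC HSF1+ responded less than WT at HSP12 (-3.37 ± 0.69, log2 ± standard error, 3 libraries per group), RTC3 (-2.57 ± 0.31), HXK1 (-2.47 ± 0.44), SOL4 (-2.44 ± 0.42), HSP42 (-1.81 ± 0.29) and SSA4 (-0.95 ± 0.25). HSP12 ended higher than in WT (2684 against 1359 CPM), HSP42 and SSA4 lower. PHO89, PHO11, PHO12 and PHO5 were more positive at 2.50 ± 0.59, 2.44 ± 0.29, 2.44 ± 0.30 and 2.16 ± 0.19. Among Msn2/4-target genes 0 rose, 19 fell and 6 did not pass (0 up and 21 down adjusted over the list alone). Their median was -1.16 (camera adjusted p = 2.95e-12, 0.306 with an estimated correlation). Of the proteasome genes 0 rose, 23 fell and 10 did not pass (0 up and 30 down adjusted over the list alone). The median was -0.30 (camera adjusted p = 1.06e-11, 0.306 with an estimated correlation). Of the ribosomal protein genes 83.3% rose, 1 fell and 22 did not pass (94.2% up and 1 down adjusted over the list alone). Their median was 0.84 (camera adjusted p = 9.12e-33, 0.306 with an estimated correlation). EdgeR called 255 genes, 155 higher and 100 lower, or 63 and 191 scaled by library size alone. Leaving out WT AzC replicate 1 gave 415 (284 higher), WT AzC replicate 2 149 (67 higher) and HSF1+ untreated replicate 3 144 (70 higher).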

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

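The tests of ribosomal protein genes after AzC, of HSF1 loss and of growth in the untreated cassette strains, both tests of the replicate 1 libraries and the tally of splits by strain were chosen after the result was seen.

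The 6 differences between strains in their response to the same treatment were singled out because an interaction test gave genes past the threshold. For hsf1∆ against HSF1+ there were 282 genes under heat shock and 221 under AzC. For the strain labelled msn2/4∆ against WT there were 351 under heat shock and 32 under AzC. For HSF1+ against WT there were 166 under heat shock and 255 under AzC.

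Chance was checked by exchanging strain labels among the libraries of each condition in 100 splits, the real one included. As many genes as in the real groups came from 17 splits for hsf1∆ and heat shock (highest other 1329), 12 for hsf1∆ and AzC (1039), 9 for the labelled msn2/4∆ strain and heat shock (614), 10 for that strain and AzC (212), 11 for HSF1+ and heat shock (779) and 11 for HSF1+ and AzC (678), so by this count chance cannot be excluded. The splits with higher counts point to a structure of the samples. Apart from the real ones, all splits as large left a strain unmixed in at least 1 condition, which adds the plain strain difference to the interaction. In the splits mixing strains in both conditions (77, 79 and 81 under heat shock for hsf1∆, the labelled strain and HSF1+, 81 each under AzC) the highest count was 3. Mixing puts strain differences into the spread within groups, which lowers the count, so this decides nothing about chance.

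For the contrasts of 2 groups of 3, only 10 splits exist, too few for a share under 0.05. In each of 12 contrasts 1 of the 10 splits, the real one, gave as many genes. The real count and the highest other were 2233 and 0 for heat shock and 1296 and 0 for AzC in WT, 1969 and 0 for heat shock in hsf1∆, 1862 and 0 for heat shock and 292 and 1 for AzC in HSF1+, and 1990 and 0 for heat shock and 1404 and 0 for AzC in the labelled msn2/4∆ strain. Untreated, they were 716 and 0 for hsf1∆, 455 and 0 for HSF1+ and 33 and 0 for the labelled strain against WT, and 189 and 1 for hsf1∆ against HSF1+, and AzC against heat shock in WT gave 1060 and 0. For AzC in hsf1∆ all 10 splits gave 0 by edgeR, like the real one, where 174 genes had an unadjusted p below 0.05 and DESeq2 called 0 as well. In the 6 contrasts whose replicate numbers pair, the 3 other splits that part every pair gave 0 genes each.

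The first pattern weighed is the near absence of an AzC response in hsf1∆. Low precision is untested, as 1 fit ties the median standard error to that in HSF1+ (1.02 times). Loss of the chaperone part alone stays open, as AzC may not have acted (ribosomal protein median -0.044, -0.56 in HSF1+). Whether AzC acted on these cells at all cannot be told apart from a response that depends on HSF1, since the slope of their change on the WT change averaged 0.004 (-0.063, 0.086 and -0.011 in the 3 libraries), where HSF1+ gave 0.528. A need for HSF1 in the whole AzC response may therefore be set beside a failure of the treatment and beside untreated libraries labelled as AzC (median chi-square per degree of freedom 11.9 across the 2 groups, 14.7 within them), either of which would change the meaning of each hsf1∆ AzC value, and no measure of AzC uptake is given in the sources used here.

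The second pattern is the shifted untreated state of both cassette strains. Deletion of HSF1 as its whole cause is argued against, since HSF1+ cells, which keep the gene, had a median of 1.56 over Msn2/4-target genes against WT, where hsf1∆ had 2.21. Both medians use the same 3 WT libraries. A lower HSF1 level in both strains stays open, as HSF1 stood at 55.4 CPM in HSF1+ and 98.4 in WT and 6 of 21 Hsf1-target genes were lower in HSF1+. The 2 deep WT libraries stay open, as thinning (1.52) keeps gene shares. A slower growth state stays open, as the ribosome biogenesis median was -0.14 over same-numbered pairs (-0.08, -0.25 and -0.14), between the bounds set for either outcome. The cassette itself or another strain difference could also account for it, and the design cannot part these.

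The third pattern is the smaller heat-shock response of the replicate 1 libraries. The slopes of replicates 1 to 3 on the mean response were 0.808, 0.976 and 0.958 in hsf1∆, 0.79, 0.941 and 0.926 in HSF1+ and 0.898, 0.992 and 0.948 in the labelled msn2/4∆ strain. Lower depth is argued against, as replicate 1 had the lowest total in 2 of the 4 heat-shocked groups. Shared handling of same-numbered cultures stays open. Heat-shocked libraries with the same number and of different strains correlated at a mean of 0.424 over 18 pairs, but a replicate 1 that is low in every strain gives such a correlation by itself, so the test decides nothing. No biological explanation was tested.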

How the results depend on the processing

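Thinning of the deep libraries, replicates 2 and 3 alone and protein-coding genes alone were tests chosen after the result was seen. Apart from left-out libraries, 207 counts and shares stayed within 1.5 times their value and 10 did not, and with a library left out 146 stayed and 4 did not. Of the named gene values 2820 kept direction and call, 20 lost the call, 1 gained it and 10 changed sign, and with a library left out 2330, 38 and 20 did so (kept, lost, changed sign). The hsf1∆ AzC contrast gave 0 calls in every setting run, 0 by DESeq2 included, with 174 genes at an unadjusted p below 0.05 by edgeR. Heat-shock calls ran from 2052 to 2358 in WT over the settings, from 1823 to 2025 in hsf1∆, from 1739 to 1932 in HSF1+ and from 1825 to 2115 in the labelled msn2/4∆ strain.

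With replicate number as a block, the calls of the HSF1+ interaction with WT under AzC went from 255 to 394 and those of the labelled msn2/4∆ strain from 32 to 49. It moved no other total by over 1.5 times, took the genes with a more positive AzC response in hsf1∆ than in HSF1+ from 34 to 73, gave HSP82 a call in the hsf1∆ interaction under heat shock (-0.59, adjusted p = 0.0278) and ended 3 list calls, the cassette chaperones after heat shock in HSF1+ (adjusted p = 0.0524) and the labelled strain (0.076) and the methionine list in untreated HSF1+ against WT (0.0502). In the contrasts whose numbers do not all correlate above 0.1 the block gave 1972 and 0 calls for heat shock and AzC in hsf1∆, 1874 and 315 in HSF1+, 1999 and 1418 in the labelled strain and 198 for untreated hsf1∆ against HSF1+. There 5, 4, 3, 4, 3, 4 and 4 of 6 libraries correlated best with their own number.

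With replicates 2 and 3 alone, the HSF1+ interactions with WT gave 281 genes under heat shock and 494 under AzC, and the share of genes called after AzC in HSF1+ with a smaller response in the labelled strain was 15.1%. With WT in place of HSF1+ the hsf1∆ interactions gave 448 and 1238 genes, which adds the differences between HSF1+ and WT by construction. With no fold minimum on the interaction 3 of the shares rose to 18.0%, 38.8% and 66.5%, as more genes then pass. Leaving out 1 library in turn gave from 1.3e+02 to 341 genes for HSF1+ against WT under heat shock, the most without WT heat-shock replicate 1, and 144 to 415 under AzC, where WT AzC replicate 1 (415), WT AzC replicate 2 (149) and untreated HSF1+ replicate 3 (144) each decided the count. Otherwise the cause was not tested. Which direction had more calls also turned for heat shock in WT with the compared groups alone (1063 higher, 1100 lower), in the labelled strain with RLE factors (971, 982), DESeq2 (975, 981) and the compared groups alone (859, 996), in HSF1+ with thinning (945, 930) and in hsf1∆ without untreated replicate 1 (986, 980) or 3 (1025, 993), and for AzC against heat shock in WT with replicates 2 and 3 alone (573, 557). Further ended calls were SSA2 in untreated hsf1∆ against WT with RLE factors (adjusted p = 0.0703), the compared groups alone (0.073) and thinning (0.0789), in the untreated labelled strain MSN4 by library size (0.0714), with the compared groups alone (0.244) and with replicates 2 and 3 alone (0.364) and DDR2 with replicates 2 and 3 alone (0.149), and BOP2 in that strain's AzC interaction with the compared groups alone (0.0603) and replicates 2 and 3 alone (0.0941). Without untreated hsf1∆ replicate 3 HSP12 in hsf1∆ was 5.604 after heat shock, -0.43 after AzC, 3.66 against WT and -3.35 in the AzC interaction.

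Values that changed sign lay near 0 and were not called. CTT1 in the hsf1∆ interaction under heat shock (-0.01) was 0.067 with RLE factors, 0.047 by library size, 0.093 with the compared groups alone, 0.067 in DESeq2, 0.031 with thinning, 0.048 with replicates 2 and 3 alone, 0.73 with WT as the reference and -0.31 to 0.34 with a library left out. HSC82 in untreated hsf1∆ against WT (-0.04) was 0.14 by library size and -0.17 to 0.064 with a library left out. HSP82 in the labelled strain's interaction under heat shock (-0.02) was 0.064 by library size and -0.19 to 0.10. After AzC in hsf1∆, SSA4 was 0.066 with replicates 2 and 3 alone and -0.10 to 0.058 with a library left out, HSP104 -0.018 to 0.20, HSP42 -0.12 to 0.22 and HSP82 -0.13 to 0.17. HSP42 in AzC against heat shock in WT was -0.085 to 0.17. The cause was not tested.

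Of 161 list calls with the preset correlation, 20 held with the estimated one and 141 did not, with no change of direction. Scaling by library size alone shifted the median gene by over 0.1 in log2, to 0.12 and 0.16 for heat shock and AzC in WT, 0.27 and 0.25 in the labelled strain, 0.16 for untreated hsf1∆ against WT, 0.11 for the heat-shock interaction of the labelled strain with WT, and -0.12 and -0.18 for HSF1+ against WT under heat shock and AzC. With the depth of these libraries and 1 spread per gene for all groups, simulated data recovered 83.6% of 1.5-fold changes after AzC in hsf1∆ and 62.7% in the interaction at an adjusted p alone. Depth was not varied in the simulation.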

Other observations

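The make-up of the strain differences and the marker levels were looked at after the result was seen. Of the 219 genes with a negative heat-shock interaction of hsf1∆ with HSF1+, 92 were called higher and 88 lower in heat-shocked WT, 18 were on the Hsf1-target list, 74 on the ribosomal protein list and 1 on the Msn2/4-target list. Under AzC the 187 negative ones held 21 Hsf1 targets, 20 Msn2/4 targets and 0 ribosomal protein genes, and 177 of them were called higher after AzC in WT. Of the 262 negative ones of the labelled msn2/4∆ strain under heat shock, 21 were Msn2/4 targets, 0 were Hsf1 targets and 215 were called higher and 23 lower in heat-shocked WT. Of the 155 genes with a more positive AzC response in HSF1+ than in WT, 151 were called lower after AzC in WT.

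MSN4 transcripts, in CPM (mean ± SD, n = 3), stood at 38.4 ± 7.53 in untreated, 115.4 ± 10.3 in heat-shocked and 68.8 ± 7.4 in AzC-treated WT, at 52.9 ± 4.82, 40.5 ± 0.471 and 37.4 ± 4.41 in the strain labelled msn2/4∆, at 27.3 ± 2, 25.4 ± 1.29 and 29.3 ± 1.2 in hsf1∆, and at 58.6 ± 6.94, 63.6 ± 5.41 and 72.6 ± 4.25 in HSF1+. LEU2, URA3 and MET17 had 0 counts in all 36 libraries, which allows up to 0.368 CPM (3 counts) in the shallowest library, for counting error only. HIS3 and LYS2 stood at 79.2 ± 7.59 and 188 ± 16.3 in untreated WT.

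Of the mating markers, the a-cell genes MFA1, MFA2, STE2, STE6 and BAR1 stood at 184 ± 28.2, 436 ± 19.7, 782 ± 41.6, 388 ± 24.8 and 290 ± 36.4 CPM in untreated WT, and the alpha-cell genes MF(ALPHA)1, MF(ALPHA)2, STE3 and SAG1 at 0.289 ± 0.194, 0.519 ± 0.0598, 4.13 ± 0.135 and 57.3 ± 8.34. Untreated hsf1∆ and HSF1+ had a lower mean at all 5 a-cell genes (BAR1 101.4 ± 9.92 and 116.1 ± 9.17, STE2 428 ± 1.2 and 584 ± 22.7), with SAG1 at 92.9 ± 6.49 and 57.4 ± 5.95.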
